A study of Mus musculus with 2 samples.

How the data were processed

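Nuclei of neonatal mouse cardiac fibroblasts that had received Tbx5 and a short hairpin RNA against Ybx1 were profiled 3 days later with a joint RNA and ATAC assay, per the labels. The series held 1 RNA library and 1 ATAC library. The deposited RNA table gave counts of UMIs per gene and nucleus, and the deposited ATAC table gave counts per peak and nucleus; both held whole numbers without normalization, which was tested on the values. Of the ATAC values, 85.5% were even, so a fragment often entered as a pair of ends. Intervals for the peaks at Tbx5 were computed on counts divided by 2. Those for promoters were computed on undivided counts and are therefore too narrow. FastQC, Cell Ranger, Cell Ranger ARC and Seurat, with the mm10 genome, were named per the submitters' processing notes; their versions, the peak caller and the rule by which nuclei were called are not given in the sources used here. Intronic reads cannot be told from exonic ones in the table.

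The barcodes of both tables were the same 5866. Nuclei needed at least 500 UMIs, at least 1000 in-peak counts and under 20% mitochondrial UMIs, and every deposited nucleus met all 3 limits. The RNA library held 59653663 UMIs and the ATAC library 139709761 in-peak counts, with medians of 8869.5 and 21018.5 per nucleus. Gene symbols were used as the table gives them. Gene positions came from a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10, in which 26292 genes of the RNA table had a position. That table gave no strand and no genome sequence was used here, so a promoter was taken as the peaks within 1000 bp of the annotated gene end with more pooled counts, which 18899 genes had, and no motifs were searched.

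RNA counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes gave 30 principal components, and the Leiden method (resolution 0.5, seed 0) was run on an exact graph of 20 nearest neighbours with shared-neighbour weights. ATAC clusters came from the ATAC table alone: 189042 peaks open in at least 1% of nuclei, TF-IDF weights, singular components 2 to 30, and the same graph and Leiden settings. The RNA of ATAC-defined clusters and the promoters of RNA-defined clusters were then compared with all other nuclei, so that the values compared had not defined the groups. A cluster was named after a cell type when at least 3 of its markers reached 20 CPM (counts scaled to a total of 1000000) and 4 times the level of the other nuclei, or, for fibroblasts, by markers above 100 CPM. A cluster whose median depth was below the sample's median divided by 3 stayed unnamed unless a marker of the class was among its 10 leading genes. A name ending in "-like" says no more than that.

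Values were pooled CPM of UMIs or of in-peak counts, with exact Poisson 95% intervals for levels, exact binomial (Clopper-Pearson) 95% intervals for shares and exact conditional binomial 95% intervals for log2 ratios. A list was summarised by the median log2 ratio over its measured members, those with at least 30 counts in all and 5 expected on the smaller side; a side with 0 counts was set to a floor of 3 counts. The interval of a list's median came from 200 Poisson redraws of the counts, and its percentile was taken among 10000 random lists of the same size matched on total count. No p-value was computed: nuclei of 1 library are not replicates, and no untreated library was analysed here, so no size of the knockdown or of the over-expression can be given. For nuclei with a UMI of Tbx5 or Ybx1 against nuclei without, each nucleus was thinned to 5100 UMIs, which kept 5291 nuclei and left out 575, and the gene itself was left out. Doublets were scored by simulation. The threshold found from the scores, 0.608, was passed by 2 nuclei, so the caller did not separate doublets, and the nuclei with the highest 5% of scores were left out as an alternative instead. The self-test drew counts from the real means for each comparison with 200 changed genes or promoters. With log2 changes of 1.0 planted, medians of 1.02 (Tbx5 split, 13147 genes), 0.98 (Ybx1 split, 13149), 0.99 (ATAC-defined clusters, 14637) and 0.99 (promoters, 18897) were recovered. Of the intervals of unchanged features, 95.4% to 95.9% held 0. The draws were independent Poisson counts, the model that the intervals assume, so this coverage was built in. Variation between nuclei and paired ATAC ends were not simulated, so the self-test does not show that the intervals cover in the real data.

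The clustering, comparisons, gene lists and naming rule were chosen before the data were examined. The 12 lists of genes were delivered and targeted genes, other reprogramming factors, sarcomere, cardiac calcium handling and conduction, natriuretic peptides, fibroblast and matrix, myofibroblast and TGF-beta response, interferon response, S phase, G2 and M phase, p53 and growth arrest, and immediate early and stress. Marker lists covered cardiomyocytes, fibroblasts, smooth muscle or pericytes, endothelium, macrophages, epicardium or mesothelium, Schwann or glial cells, lymphoid cells, erythroid cells and cycling cells, and mitochondrial and ribosomal protein transcripts served as a measure of cytoplasmic RNA. Named genes were list members, as 2 to 4 examples with the highest level or the largest ratio, and up to 10 genes each way outside the lists with at least 100 UMIs and 20 nuclei on the higher side, ranked by the bound of the interval nearest to no difference; mitochondrial, ribosomal protein and predicted gene models were passed over. Genes named for an RNA-defined cluster, for free RNA and for the 8 cardiomyocyte-like nuclei were chosen after their values were seen. Alternatives covered the Leiden resolution, the number of components, doublets, thinning, normalization, the promoter window and presence or absence per peak; others, chosen after the data were seen, left out groups of nuclei, split nuclei by sex-linked RNA or thinned the ATAC counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9 were used.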

Results

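Cardiac fibroblasts from C57BL/6 mice aged 1 to 3 days carried viruses for Tbx5, a T-box transcription factor of heart development, and for a short hairpin RNA against Ybx1, a protein that binds mRNA and acts on its translation and stability. Nuclei were isolated 3 days after transduction, and RNA and open chromatin (ATAC) were read from the same nuclei. Each assay gave 1 library of this 1 condition, so there were no replicates, and no untreated library was analysed here. The barcodes of both libraries were the same 5866. The RNA library held 59653663 UMIs over 32285 genes, of which 22995 had a count, with a median of 8869.5 UMIs (range 1004 to 24999) and 3339 genes per nucleus. The ATAC library held 139709761 counts in 211652 peaks, with a median of 21018.5 (range 5004 to 69944) per nucleus. All intervals are 95% intervals and cover counting error only. Ratios compare nuclei with other nuclei of the same library, not with untreated cells. Mitochondrial transcripts made up 9.87% of UMIs, ribosomal protein transcripts 11.4% and the nuclear RNA Malat1 1.25%.

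The RNA showed which cell types and states were present. Fibroblast-like nuclei made up 84.7% (83.8% to 85.6%) and cycling fibroblast-like nuclei, which held mitotic genes such as Top2a and Cenpf, a further 8.86%; together they were 93.6% (92.9% to 94.2%). The rest were 138 smooth muscle- or pericyte-like nuclei (2.35%), with 937 CPM (UMIs per 1000000) of the smooth muscle myosin Myh11 against 6.50 in all other nuclei, 83 endothelial-like nuclei (1.41%) with the junction gene Cdh5, 63 epicardial- or mesothelial-like nuclei (1.07%) with the mesothelin gene Msln, and 41 macrophage-like nuclei (0.699%) with the lysozyme gene Lyz2. No cluster of Schwann, lymphoid or erythroid nuclei was found. A cluster of 43 nuclei with a median of 1628 UMIs was left unnamed. The fibroblast-like name needed only fibroblast markers above 100 CPM, with no ratio to other nuclei. Clusters of other names met that limit too, the macrophage-like one with 9 markers and the endothelial-like one with 7. The name thus went to clusters that met no other class, and the fibroblast-like shares are not by themselves evidence of fibroblast identity.

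Cardiomyocyte-like nuclei numbered 8, or 0.136% (0.0589% to 0.269%). They held 511 of the library's 590 UMIs of Myh6, the main myosin heavy chain of the adult mouse heart, and 250 of the 555 UMIs of the giant sarcomere protein gene Ttn. Tbx5 was seen in 1 of them. The other 5858 nuclei held 1.33 CPM of Myh6. The share named cardiomyocyte-like was 0% at resolution 0.3 (up to 0.0629%), but 7.09% at resolution 1.0, 29.4% with 15 components and 18.7% without the nuclei of highest doublet score, because 7 of the 8 nuclei then lay in clusters of 416, 1722 and 1046 nuclei that took a name from them. Without the 8 nuclei it was 0% in all 4 settings, and the smooth muscle- or pericyte-like share was 5.55% at resolution 0.3.

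**Figure D1:**
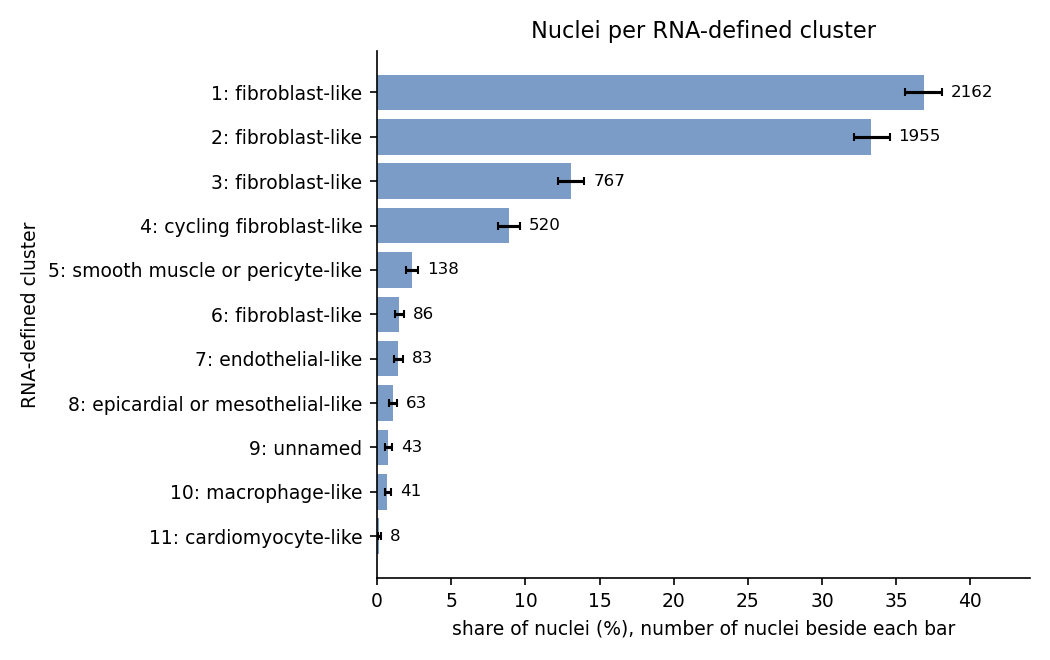
Share of the 5866 nuclei in each of the 11 RNA-defined clusters (percent, bars, with exact binomial 95% intervals), by cluster name. Clusters 1 and 2, both fibroblast-like, hold 36.9% and 33.3%, and the cardiomyocyte-like cluster 0.136%.

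Tbx5, at 119796514 to 119885220 on chromosome 5 (mm10), reached 77.7 CPM (75.53 to 80.02), with 4638 UMIs in 2807 nuclei (47.9%). Ybx1, at 119277327 to 119296265 on chromosome 4, reached 40.7 CPM (39.1 to 42.4), with a UMI in 28.2% of nuclei, and in 26.8% of macrophage-like and 26.2% of fibroblast-like nuclei. Macrophage-like nuclei, which should lack RNA of their own Tbx5 gene, held 23.4 CPM against 76.1 in fibroblast-like nuclei; a UMI was seen in 14.6% at a median of 3346 UMIs, against 48.2% at 8973.5. With every nucleus thinned to 1000 UMIs the shares were 0 of 41, which allows up to 8.60%, and 7.93%. Tbx5 was 71.5 CPM in endothelial-like nuclei, close to the fibroblast-like level. Ybx1 was higher in endothelial-like (102 CPM, 76.7 to 134) than in fibroblast-like nuclei (33.9), and the interval in macrophage-like nuclei (50.7, 27.0 to 86.7) held the fibroblast-like level. A UMI of the delivered Tbx5 sequence cannot be told from one of the mouse's own gene, and reads shared with near-identical processed pseudogenes leave the Ybx1 level uncertain. Neither the size of the over-expression nor that of the knockdown can be given without an untreated library.

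Fibroblast genes stood at high levels: Col1a1 and Col1a2, which encode the chains of type I collagen, reached 6102 and 5767 CPM, and 15 of 18 fibroblast and matrix genes were seen in most nuclei. The smooth muscle actin gene Acta2 reached 6229 CPM and the myofibroblast list a median of 550.3. Heart genes varied widely. The troponin gene Tnnt2 reached 1592 CPM and the ryanodine receptor Ryr2, the calcium release channel of heart muscle, 627, while 10 of 20 sarcomere genes were seen in under 5% of nuclei, among them Myh6 at 9.89 CPM (0.955% of nuclei) and Myh7 at 0.235. The median was 8.07 CPM for the sarcomere list and 47.1 for calcium handling. Nppa, the atrial natriuretic peptide gene, reached 46.2 CPM (13.2% of nuclei) and Nppb 5.40. Among other reprogramming factors (median 58.9 CPM) Gata4 reached 155 and Mef2c 58.9. Medians were 18.5 CPM for the interferon list, where Bst2 was at 530.0, 15.9 for S phase, 17.7 for G2 and M phase, 58.4 for the p53 list, where the cell-cycle inhibitor Cdkn1a was at 717, and 22.4 for immediate early genes.

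UMIs of several of these genes were frequent in nuclei that should lack them. Macrophage-like nuclei held 1502 CPM of Tnnt2, which is 90.7% of the level in fibroblast-like nuclei, 4811 of Col1a1 against 6345, and 97.5 of Gata4 against 162, so a UMI of these genes does not show expression by the nucleus. The same holds for Postn, Dcn, Acta2 and Myl7, whose levels in macrophage-like nuclei were 103%, 104%, 71.3% and 58.5% of those in fibroblast-like nuclei. Atp2a2, the sodium-calcium exchanger gene Slc8a1 and Gja1 were at 67.0%, 59.3% and 55.5%. Whether macrophage-like nuclei expressed these genes themselves was not tested, so their levels do not show RNA from other cells. Ryr2 was 226 CPM in macrophage-like and 678 in fibroblast-like nuclei; at 1000 UMIs per nucleus a UMI was seen in 14.6% and 42.9%. Nppa was 11.7 and 47.0 CPM; in macrophage-like nuclei it was seen in 7.32% at full depth but, at 1000 UMIs per nucleus, in 0 of 41, which allows up to 8.60%, against 3.16% of fibroblast-like nuclei. Some cell type markers stayed apart: Lyz2 was 3379 CPM in macrophage-like and 3.94 in fibroblast-like nuclei. Cdh5 was 495 CPM in endothelial-like and 0.585 in fibroblast-like nuclei. The macrophage marker Csf1r was less distinct, at 85.8 CPM in macrophage-like and 18.3 in fibroblast-like nuclei, of which 13.5% held a UMI. The fibroblast markers Col1a1, Postn and Dcn did not stay apart, as given above.

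ATAC counts at Tbx5 stood out in 1 of the 18 peaks at the gene, where delivered Tbx5 DNA cannot be told from the mouse's own gene. A peak at 119882769 to 119883692 on chromosome 5, 1528 bp inside the gene's end coordinate, held 11671 counts (83.5 CPM of in-peak counts) and had a count in 52.4% of nuclei (51.1% to 53.7%). The next highest peak of the locus held 2277. The peak was higher in nuclei with a Tbx5 UMI than in those without (log2 0.22, 0.14 to 0.30), while the other 17 peaks together were lower (-0.13, -0.20 to -0.05). Within RNA cluster 1 the other peaks did not differ beyond counting error (0.03, -0.10 to 0.16), nor did they in nuclei with Xist (-0.07, -0.19 to 0.05), while they were lower in RNA cluster 2 (-0.15, -0.27 to -0.03) and in nuclei with Y-linked RNA (-0.13, -0.26 to -0.0021). The high peak was 74.4, 102 and 65.0 CPM in RNA clusters 1, 2 and 3. It was 73.6 in the cycling cluster, 92.6 in smooth muscle- or pericyte-like nuclei and 89.3 in cluster 6. Tbx5 RNA was 111, 28.9 and 11.3 CPM in these last 3 groups, so the peak did not follow Tbx5 RNA across all clusters. The other 17 peaks together were 73.8, 167 and 140 CPM in the same 3 groups, so they too were lowest where Tbx5 RNA was highest.

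**Figure D2:**
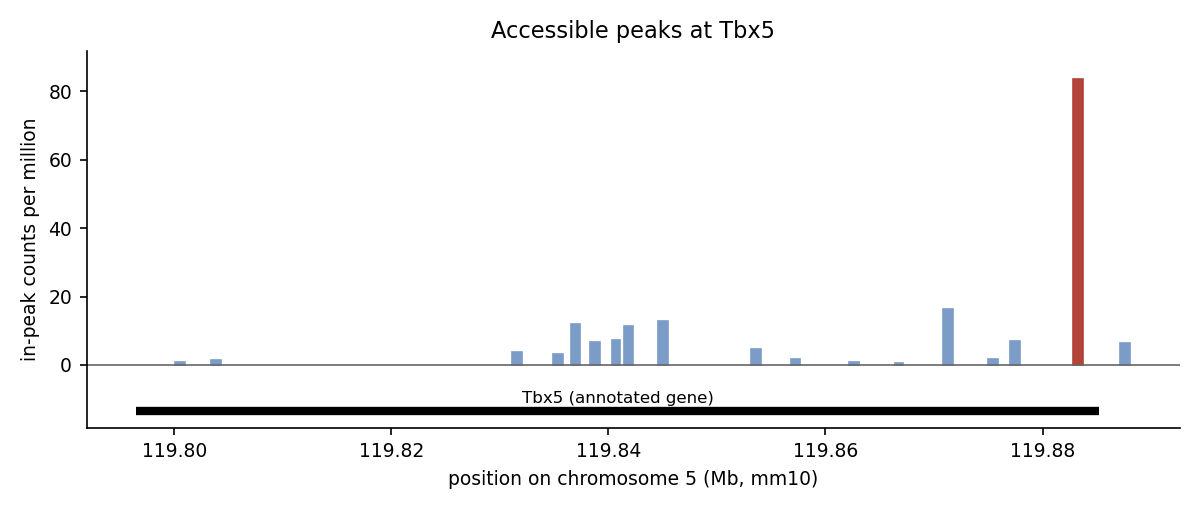
CPM of in-peak counts (bars) of the 18 peaks at the Tbx5 locus on chromosome 5 (mm10 position), with the annotated gene drawn under them. The peak at 119882769 to 119883692 holds 83.5 CPM, 5.13 times the next highest.

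Among the fibroblast-like nuclei, the clusters made from RNA differed in the genes named here. Apart from Tbx5 and Ybx1, these were chosen after their values were seen. The genes named here helped to form the clusters. Cluster 1 (2162 nuclei) held more of Rgs6, a regulator of G protein signalling (68.6 CPM against 9.79 in all other nuclei), of the elastin gene Eln (166 against 45.4) and of the endothelin receptor Ednrb, and its Tnnt2 was 2283 CPM. Cluster 2 (1955 nuclei) held more of Nat8l, which makes N-acetylaspartate (108 against 13.7), of the secreted protein gene Coch (232 against 30.7), of the potassium channel Kcnma1 (43.4 against 6.21), of the growth factor Pdgfb, and of Nppa (96.8 against 20.3). Cluster 3 (767 nuclei) held more of Ptgs2, which makes prostaglandins (111 against 22.5), with Acta2 at 9740 CPM. Cluster 6 (86 nuclei) held the matrix genes Mfap4, Aspn and Dpt, with the collagen-crosslinking enzyme gene Lox at 1555 CPM. Tbx5 was 68.6, 103 and 38.2 CPM in clusters 1, 2 and 3, 111 in the cycling cluster, 28.9 in smooth muscle- or pericyte-like nuclei and 11.3 in cluster 6. Ybx1 was 29.7, 43.9 and 20.01 in clusters 1, 2 and 3 and 105 in the cycling cluster.

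Clusters made from open chromatin alone asked whether nuclei that differ in chromatin differ in RNA. There were 7, of which 4 held 1648, 1596, 1349 and 1052 nuclei. The clusters of both assays overlapped in part: RNA cluster 1 gave 1129 nuclei to ATAC cluster 3, RNA cluster 2 gave 1159 to ATAC cluster 1, and RNA cluster 3 gave 531 to ATAC cluster 4. ATAC depth differed between them, with medians of 22705, 30782, 13809 and 16187.5 counts.

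The division into these 4 clusters depended on depth and resolution. With ATAC counts thinned to 5000 per nucleus, 79.0% of cluster 3 and 92.9% of cluster 4 lay in 1 merged cluster of 2228 nuclei, so these were not told apart at equal depth. The merged cluster had medians of 0.62 for myofibroblast genes, 0.56 for fibroblast genes, 0.38 for interferon genes, -0.39 for calcium handling, -0.88 for G2 and M phase and 0.0092 for sarcomere genes, so the lower myofibroblast and slightly higher calcium handling medians given for cluster 3 alone did not hold there. At resolution 0.3 clusters 3 and 4 merged again, in 2545 nuclei (myofibroblast 0.67, fibroblast 0.63, calcium handling -0.44, sarcomere -0.093), and clusters 1 and 2 merged in 3101 nuclei (natriuretic peptides 2.04, calcium handling 0.33, sarcomere 0.15, fibroblast -0.64). At resolution 1.0 the best matches held 53.5%, 40.5%, 35.4% and 53.3% of clusters 1 to 4, so values given for that setting are those of a part.

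ATAC cluster 4 was rich in myofibroblast RNA. The myofibroblast and TGF-beta response list was higher than in all other nuclei, with a median log2 ratio of 0.95 (0.93 to 0.98) and 11 of 13 measured genes higher: Acta2 was 10065 CPM against 5293 (log2 0.93, 0.92 to 0.94), the smooth muscle actin Actg2 286 against 37.2 (2.94, 2.86 to 3.03) and Lox 813 against 226 (1.85, 1.81 to 1.89). Fibroblast genes were higher as well (median 0.34, 0.28 to 0.48, 15 of 18), with Col1a1 at 7918 CPM against 5659 and Postn, a matrix protein of activated fibroblasts, at 399 against 184, while Pdgfra, a growth factor receptor of fibroblasts, was 90.6 against 221 (-1.29). Smooth muscle and pericyte markers were higher (1.98, 1.90 to 2.04, 9 of 10), with Myh11 at 124 against 9.35; this cluster held 116 of the 138 smooth muscle- or pericyte-like nuclei. Without such nuclei the myofibroblast median was 0.83 (0.81 to 0.86, 11 of 13 higher), with Acta2 at 8957 against 5241 (0.77), Lox at 829.6 against 225 (1.88) and Actg2 at 96.0 against 32.2 (1.58, 1.46 to 1.69), so most of its Actg2 came from them; their markers were then at 1.16, with Myh11 at 17.2 against 4.16. Calcium handling genes were lower (-1.19, 9 of 12 lower), with Ryr2 at 308 against 704 (-1.19, -1.24 to -1.14) and the connexin Gja1 at 96.8 against 238. Sarcomere genes were lower (-1.09, 2 of 18 higher; -0.72 without the cardiomyocyte-like nuclei), and Nppa was 11.7 against 54.7 (-2.22). Immediate early genes were higher (0.29, 6 of 9), with Jun at 62.4 against 30.6, but the list was at -0.088 and -0.096 in the clusters merged with cluster 3 at resolution 0.3 and with ATAC counts thinned. Tbx5 was 32.6 against 88.8 (-1.44). Outside the lists, Igfbp2, Galnt16, Aoc3, Acan and Adamts12 were higher, and Kcnma1, Greb1 and Ptprn2 lower.

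ATAC cluster 2 was rich in calcium handling RNA. That list was higher (median log2 0.65, 0.59 to 0.68, 9 of 12), with Ryr2 at 872 CPM against 551 (0.66, 0.63 to 0.69), the calcium pump of the sarcoplasmic reticulum Atp2a2 at 672 against 406 (0.73, 0.69 to 0.76) and the atrial and conduction connexin Gja5 at 55.1 against 21.5 (1.36, 1.22 to 1.49). Nppa was 77.1 against 36.7 (1.07, 0.96 to 1.18) and Gata4 195 against 142 (0.46, 0.39 to 0.52). Nppb was lower, so the natriuretic pair had a median of 0.46 with 1 of 2 higher. That median turned direction in nuclei with Y-linked RNA. Sarcomere genes had a median of 0.67 (0.56 to 0.83, 15 of 18 higher), but 0.28 (0.09 to 0.44, 12 of 18) without the 8 cardiomyocyte-like nuclei; Myh6 was then 0.93 against 1.45, Ttn 8.23 against 4.17 (0.98) and the atrial light chain Myl7 241 against 151 (0.67), while Tnnt2 (-0.07) was about level. G2 and M genes were higher (0.74, 13 of 13), with Top2a at 97.0 against 57.9, and S phase genes had a median of 0.26. Myofibroblast genes were lower (-0.48, 0 of 13 higher), with Lox at 176 against 393 (-1.16), and fibroblast genes were lower (-0.28, 3 of 18 higher). Outside the lists, Kcnma1 (50.1 against 9.18), the desmosome gene Dsp (118 against 29.2), Tac2 and Tenm4 were higher, and Myh11 and Tll1 lower. The sarcomere median was 1.23 in the matching part at resolution 1.0, 0.030 with components 2 to 15 (49.9% of the cluster), 1.27 in nuclei with Xist and 0.41 in those with Y-linked RNA. The last 2 values include cardiomyocyte-like nuclei. Of all 8 such nuclei, 6 lay in this cluster, and 4 of the 8 held Xist alone and 2 Y-linked RNA alone. The 2 values therefore do not show a difference by sex. The G2 and M median was -1.25 in the matching part at resolution 1.0 and 0.49 with ATAC counts thinned, and the S phase median -0.49 and 0.43, with 0.59 for components 2 to 15.

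ATAC cluster 1 held more natriuretic peptide RNA (median log2 1.30, 1.15 to 1.48, 2 of 2): Nppa was 67.8 CPM against 37.0 (0.88) and Nppb 10.5 against 3.21 (1.72, 1.39 to 2.05). Pdgfra was 364 against 124 (1.56), although fibroblast genes as a list were lower (-0.44, -0.48 to -0.39, 3 of 18 higher), with Col1a1 at 5197 against 6489. Myofibroblast genes were lower (-0.39, 2 of 13 higher), as were calcium handling genes (-0.14), interferon genes (-0.32) and other reprogramming factors (-0.23), among them the T-box factor Tbx20 at 95.6 against 301 (-1.65). The calcium handling and other reprogramming medians were 0.33 and 0.099 in the cluster merged with cluster 2 at resolution 0.3. Calcium handling also turned direction in nuclei with Y-linked RNA. S phase (0.34, 12 of 12) and G2 and M genes (0.29, 13 of 13) were higher, and Tbx5 was 96.4 against 69.8 (0.47, 0.38 to 0.55). Outside the lists, Nat8l was 109 against 18.3 (2.58, 2.46 to 2.70), and Pdgfb, the chemokine Ccl20 and the retinoic acid-degrading enzyme Cyp26b1 were higher, while Rgs6 (4.54 against 42.3), Sphkap and Fndc1 were lower. The natriuretic median was 0.61 with ATAC counts thinned, and the fibroblast median was -0.21 with ATAC counts thinned and -0.22 with components 2 to 15. The higher cell-cycle medians did not hold in 2 settings: in the matching parts they were -1.37 for G2 and M and -0.25 for S phase at resolution 1.0, and -0.33 and -0.061 with components 2 to 15 (47.7% of the cluster). The sarcomere median, -0.83, was -0.35 without the cardiomyocyte-like nuclei and -0.29 in nuclei with Y-linked RNA.

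ATAC cluster 3 held more interferon-response RNA (median log2 0.53, 0.41 to 0.58, 11 of 13 higher), with the antiviral genes Ifit3 at 17.1 CPM against 8.14 (1.07, 0.83 to 1.31) and Ifit1 at 41.2 against 22.1 (0.90). Tnnt2 was 2486 against 1305 (0.93, 0.91 to 0.95) and Tbx20 417 against 183 (1.19, 1.14 to 1.24), with other reprogramming factors at a median of 0.16, calcium handling at 0.10 and sarcomere genes at 0.21. Fibroblast genes were higher (0.25, 0.14 to 0.28, 14 of 18), with Col1a2 at 7198 against 5310 and the matrix proteins Mgp and Dcn at 1296 against 718 and 747 against 451. S phase (-0.72, 12 of 12 lower) and G2 and M genes (-1.24, 13 of 13 lower) were lower, with Top2a at 29.3 against 79.2, and Cdkn1a was 801 against 691. Myofibroblast genes were lower (-0.38, 4 of 13 higher), with Acta2 level (0.00), and Nppa was 17.6 against 55.4 (-1.66). Outside the lists, Rgs6 (80.8 against 15.1) and Eln (194 against 55.3) were higher. In the matching part at resolution 1.0 the medians were -0.13 for fibroblast, -0.39 for G2 and M and 0.84 for sarcomere genes. In nuclei with Xist they were 0.14 for fibroblast and -0.66 for sarcomere genes. The Xist values include cardiomyocyte-like nuclei, and without such nuclei the sarcomere median over both sexes was 0.19.

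The p53 list stayed between -0.16 and 0.03 in these 4 clusters, and Schwann markers, with 3 of 6 measured, between -0.40 and 0.35. Of 7 lymphoid markers 1 was measured, and of 6 erythroid markers 0. Cardiomyocyte markers had medians of -0.35, 0.59, 0.42 and -0.996 in clusters 1 to 4 without the cardiomyocyte-like nuclei. The 3 small ATAC clusters matched cell types. Endothelial markers were higher in cluster 5 (3.41, 4 of 4 measured), epicardial markers in cluster 6 (2.92, 4 of 4), and cluster 7 (43 nuclei) held 36 of the macrophage-like nuclei.

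**Figure D3:**
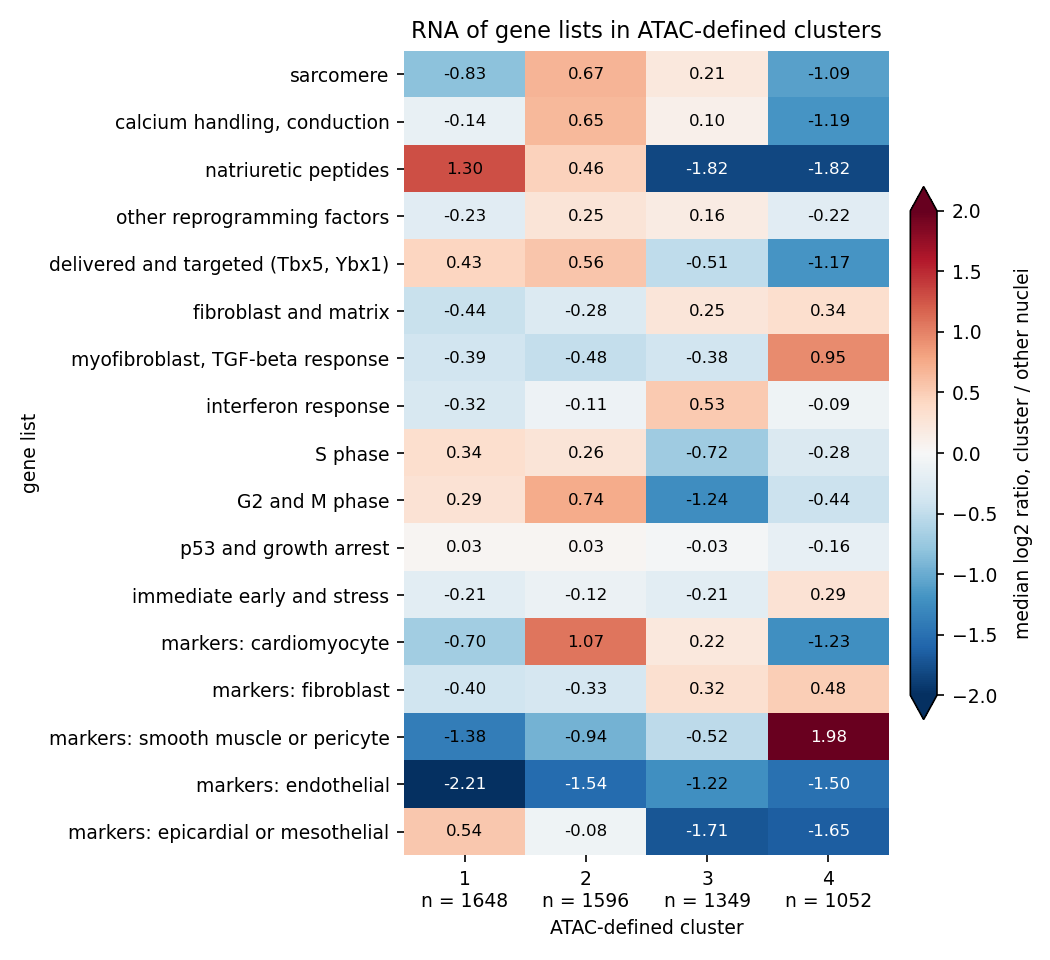
Median log2 ratio of RNA of each gene list (vertical) in ATAC-defined clusters 1 to 4 (horizontal) against all other nuclei, by colour with the value printed. The myofibroblast list reaches 0.95 in cluster 4 and the calcium handling list 0.65 in cluster 2.

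Promoter accessibility across RNA-defined clusters asked the converse question. The intervals here rest on undivided counts and are too narrow, since a fragment often entered as a pair of ends. Ratios are relative to the median of all promoters only where said. In cluster 3 promoters of myofibroblast genes were more open (median log2 0.20, 0.14 to 0.28, 11 of 13), with Lox at 31.1 CPM of in-peak counts against 19.3 (0.68), the smooth muscle calponin Cnn1 at 17.3 against 11.9 (0.54) and Thbs1 at 83.4 against 69.8 (0.26), while promoters of cardiomyocyte markers (-0.41, 2 of 12 higher) and calcium handling genes (-0.26, 4 of 14 higher) were less open, with the calcium release gene Trdn at 3.31 against 7.63 (-1.21). The medians were small, and the myofibroblast one was 0.11 at resolution 1.0.

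In cluster 2 the median of all promoters was -0.12, so values are given relative to it. Promoters of cardiomyocyte markers were more open (0.57, 0.38 to 0.71, 10 of 12 above), with Ttn at 7.99 against 4.89 (0.83), Tnnc1 at 5.86 against 3.64 (0.81) and Myl7 at 4.73 against 3.07 (0.74), and so were those of Nppa (9.87 against 6.07, log2 0.82) and Nppb (14.6 against 9.28, log2 0.77). The promoter of Tnnt2 went the other way, at 15.5 against 23.2 (-0.46), as did those of Gata4 (15.4 against 20.2, log2 -0.28) and Lox (13.3 against 24.9, log2 -0.78). Relative medians were 0.17 for calcium handling, -0.03 for other reprogramming factors, -0.09 for fibroblast genes, -0.12 for myofibroblast genes, -0.08 for interferon, -0.10 for S phase, -0.04 for G2 and M phase, 0.10 for p53 and -0.09 for immediate early genes. The unadjusted cardiomyocyte marker median was 0.45 in all nuclei and 0.71 in those with Y-linked RNA.

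In cluster 1 the promoters of Nppa (4.68 against 8.98, log2 -0.94) and Nppb (6.58 against 13.7, log2 -1.06) were less open and that of Tnnt2 more open (28.0 against 16.2, log2 0.79, 0.68 to 0.90), with fibroblast genes at 0.12 (14 of 18 higher). In the cycling cluster S phase promoters had a median of 0.27 (12 of 12 higher) and G2 and M promoters 0.24 (0.16 to 0.33, 12 of 13), with the spindle gene Tpx2 at 32.4 against 22.9; over gene bodies with flanks the latter was 0.11. In smooth muscle- or pericyte-like nuclei the median of all promoters was 0.09, which was not subtracted here. Such nuclei had more open promoters of their markers (0.35, 0.10 to 0.60, 6 of 10 higher, but 0.078 in nuclei with Y-linked RNA), with a lower bound close to that median. Among them were those of Myh11 (22.1 against 10.6, log2 1.06, 0.65 to 1.45), and the promoter of Acta2 was more open too (54.7 against 31.3, log2 0.81). Epicardial-like nuclei had more open promoters of theirs (1.06, 4 of 4 higher, 0.53 over gene bodies with flanks and 0.48 in nuclei with Xist), such as Upk3b (45.9 against 6.79, log2 2.76). Relative to all promoters, which had medians of 0.21 and 0.27, the log2 ratio of Cdh5 was 2.36 in endothelial-like nuclei and that of Lyz2 2.51 in macrophage-like nuclei. The Lyz2 value rested on 15 counts, and unadjusted it was 2.79. Of the other macrophage markers with a promoter peak, Cd68 was at 1.23 unadjusted and Mrc1 had 0 counts. The lymphoid marker Cd3d, with 0 UMIs of RNA in these nuclei, had 18 counts and an unadjusted ratio of 2.84. The Lyz2 ratio alone therefore does not show the cell type. Promoter peaks were found for 15 of 20 sarcomere genes, 7 of 9 endothelial, 3 of 9 macrophage and 1 of 6 erythroid markers, and for neither Tbx5 nor Ybx1. As fewer than 80% of their members had a promoter peak, the check of these as lists is void, and values are given for single genes alone. A promoter peak here lay within 1000 bp of an annotated gene end, so a start elsewhere in the gene would be missed. All 18 peaks at Tbx5 lay outside that window, so an open promoter of Tbx5 or Ybx1 is not excluded.

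**Figure D4:**
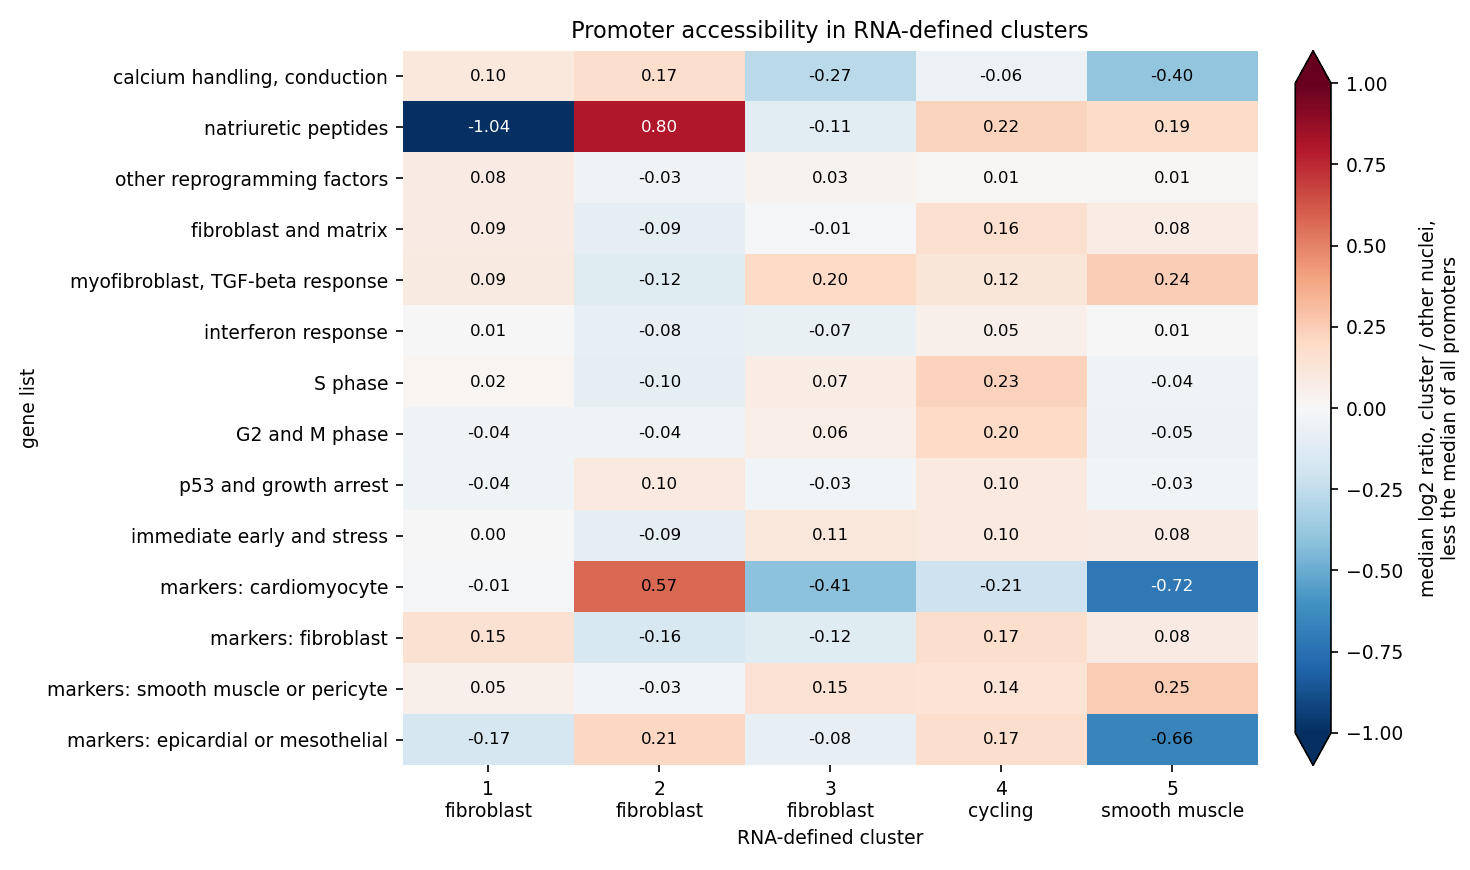
Median log2 ratio of promoter counts of each list (vertical) in RNA-defined clusters 1 to 5 (horizontal) against all other nuclei, less the median of all promoters, by colour with the value printed. Cardiomyocyte marker promoters reach 0.57 and those of the natriuretic peptides 0.80 in cluster 2.

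Nuclei with a Tbx5 UMI were set against nuclei without, after thinning to 5100 UMIs, since nuclei may carry different amounts of the delivered factor. The amount per nucleus was not measured, and absence of a UMI is not absence of expression. Presence of a UMI need not mean expression either, since macrophage-like nuclei held 23.4 CPM of Tbx5 against 76.1 in fibroblast-like nuclei. With Tbx5 were 1670 nuclei and without 3621. Myofibroblast genes were lower with Tbx5 (median log2 -0.36, -0.40 to -0.34, 12 of 13 lower): Acta2 was 5151 CPM against 6571 (-0.35, -0.37 to -0.34), Actg2 32.2 against 104 (-1.70, -1.89 to -1.51) and Lox 202 against 378.0 (-0.91, -0.98 to -0.83). Fibroblast genes were lower (-0.18, -0.26 to -0.12, 16 of 17 lower), with Col1a1 at 5264 against 6238 and Postn at 181 against 248 (-0.46), while Pdgfra was higher, at 232 against 178 (0.38, 0.30 to 0.46). Calcium handling genes were higher (0.26, 0.16 to 0.32, 8 of 11), with Ryr2 at 712 against 589 (0.27, 0.23 to 0.32) and Atp2a2 at 510 against 451 (0.18). Nppa was 57.6 against 36.4 (0.66, 0.49 to 0.83), and the natriuretic pair had a median of 0.57.

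Sarcomere genes had a median of -0.01 (8 of 17 higher) between nuclei with and without Tbx5, and of 0.22 (0.05 to 0.34, 11 of 14 higher) without the 8 cardiomyocyte-like nuclei. Other reprogramming factors had a median of 0.02, with Gata4 at 162 against 148 CPM, interferon genes 0.02, p53 genes 0.03 and immediate early genes -0.22 (7 of 9 lower). G2 and M genes were higher (0.43, 0.38 to 0.56, 13 of 13), with Top2a at 96.0 against 62.1 (0.63), as were S phase genes (0.23, 12 of 12). Smooth muscle and pericyte markers were lower (-0.85), as were fibroblast (-0.24) and endothelial markers (-0.64), while macrophage markers, with 2 of 4 measured higher, were at -0.25 (-0.96 to 0.28); epicardial markers were at 0.38 and cardiomyocyte markers at 0.02, or 0.30 without the cardiomyocyte-like nuclei. Ybx1 was 51.3 against 39.5 (0.38, 0.22 to 0.55). Outside the lists, the adhesion gene Clstn2 (24.1 against 10.8, log2 1.16), Tac2 (18.8 against 8.72), Nnat (15.4 against 7.69) and Saa3 (142 against 85.5) were higher. Myh11 (7.75 against 39.5, log2 -2.35), Lrrc32, which presents latent TGF-beta (14.2 against 41.4, log2 -1.54), and the matrix protease Adamts12 (23.1 against 58.0, log2 -1.33) were lower.

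The share of thinned nuclei with a Tbx5 UMI was 29.6%, 39.5% and 16.3% in RNA clusters 1, 2 and 3, 41.6% in the cycling cluster and 1.20% in cluster 6. Median depths before thinning were 9080 UMIs with Tbx5 and 9621 without. Within RNA cluster 1 the medians were -0.15 for myofibroblast genes, 0.14 for sarcomere genes, 1.11 for natriuretic peptides, -0.027 for S phase and -0.14 for G2 and M phase. Without the cycling cluster they were -0.22 for G2 and M phase, 0.056 for S phase and 0.36 for natriuretic peptides. With 2 or more Tbx5 UMIs they were 0.83 for G2 and M phase, -0.31 for fibroblast genes and 1.01 for natriuretic peptides, which stood at 0.084 in nuclei with Xist and 1.12 in those with Y-linked RNA. Thinned to 10200 UMIs, the medians were 0.76 for G2 and M phase, -0.24 for sarcomere genes and -0.046 for immediate early genes.

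Nuclei with a UMI of Ybx1, the knockdown target, numbered 903 of those thinned, against 4388 without. Cell-cycle genes were higher with Ybx1: G2 and M genes had a median log2 ratio of 1.07 (0.97 to 1.20, 13 of 13 higher) and S phase genes of 0.84 (0.58 to 0.91, 12 of 12). Top2a, which untangles replicated DNA, was 138 CPM against 59.3 (1.22, 1.08 to 1.35), the proliferation marker Mki67 88.4 against 44.6 (0.99), the nucleotide-making enzyme Rrm2 26.1 against 9.79 (1.41) and the replication clamp Pcna 0.16 higher. Myofibroblast genes were lower (-0.22, 10 of 13 lower), with Acta2 at 4966 against 6360 (-0.36), and so were fibroblast genes (-0.17, 14 of 17 lower), with Col1a1 at 5264 against 6067. Medians were 0.08 for calcium handling, 0.23 for natriuretic peptides, -0.03 for other reprogramming factors, where the heart factor Hand2 was 25.9 against 36.6 (-0.50), -0.01 for interferon, -0.05 for p53 and -0.02 for immediate early genes. The sarcomere median was -0.22 (12 of 17 lower) and 0.0022 (7 of 14 higher) without the cardiomyocyte-like nuclei.

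Endothelial markers were higher with Ybx1 (1.11, 7 of 8), with Cdh5 at 10.6 against 2.46; medians were 0.28 for epicardial, -0.34 for smooth muscle and -0.05 for macrophage markers. Tbx5 was 101 against 77.6 (0.38, 0.23 to 0.53). Outside the lists, the keratin Krt79 (25.8 against 8.27, log2 1.64, 1.30 to 1.98), Ptprn2 (44.7 against 18.1, log2 1.31) and the mitotic genes Plk1, Anln, Prc1 and Hmmr were higher, and the retinaldehyde dehydrogenase Aldh1a1 (43.4 against 71.3, log2 -0.72), Lrrc32 and Frzb lower. A Ybx1 UMI was seen in 35.2% of thinned cycling nuclei, 38.5% of endothelial-like nuclei and 14.0%, 19.6% and 7.72% of RNA clusters 1, 2 and 3. Within RNA cluster 1 the medians were -0.43 for G2 and M phase, 0.16 for S phase, -0.091 for myofibroblast genes and -0.084 for fibroblast genes. Without the cycling cluster they were 0.69 for G2 and M phase and 0.30 for S phase, and with 2 or more Ybx1 UMIs 2.12, 1.61 and, for myofibroblast genes, -0.47.

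**Figure D5:**
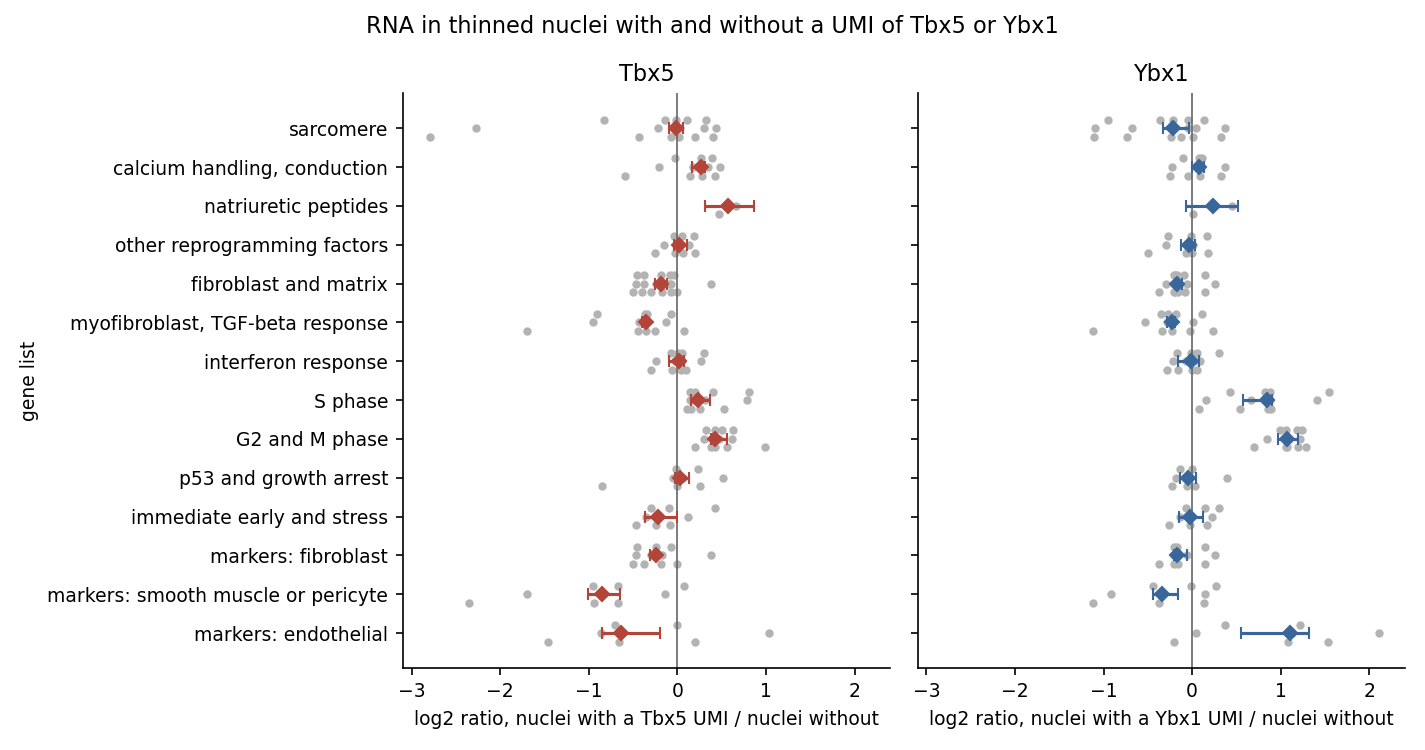
Median log2 ratio of each gene list (vertical) between thinned nuclei with and without a UMI of Tbx5 or Ybx1 (horizontal, coloured points with 95% intervals for counting error; grey points are the measured genes). The myofibroblast list lies at -0.36 for Tbx5 and -0.22 for Ybx1, and the G2 and M list at 0.43 and 1.07.

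Whether heart-gene RNA lay in nuclei with less fibroblast RNA was asked by the number of sarcomere UMIs per thinned nucleus. Of 5291 nuclei, 5276 held 5 or more, mostly from widespread genes such as Tnnt2 and Tpm1, and 0 nuclei held none, so the planned groups hardly divided them; the fibroblast list stood at 21313 CPM in the main group. A list restricted to sarcomere genes seen in under 10% of nuclei, chosen after the values were seen, divided them better. With 0, 1, 2 to 4 and 5 or more UMIs of these genes (4289, 802, 171 and 29 nuclei) the fibroblast list stood at 21660.3, 19796, 17241 and 14119.6 CPM, and Postn at 236, 204, 137 and 109. Pdgfra, also of that list, stood at 190, 222, 215 and 109, so not every fibroblast gene fell step by step. Ryr2 stood at 599, 698, 902 and 1339 and Nppa at 38.8, 52.1, 55.1 and 353. The myofibroblast list stood at 13362, 12236, 10134 and 13678. Without the cardiomyocyte-like nuclei the last group held 22 nuclei, with the fibroblast list at 16087 CPM, Postn at 116, Ryr2 at 1232, Nppa at 187 and the myofibroblast list at 13650.2.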

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

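The alternatives that left out groups of nuclei, split nuclei by sex-linked RNA, thinned the ATAC counts or restricted the sarcomere list were chosen only after the data were seen. No paired analysis was possible because each assay had 1 library. The filters removed no nucleus, so all deposited nuclei gave the same values, and the motif search was not run for lack of a genome sequence. Of 730 log2 ratios under an alternative, over 76 results, 31 turned direction, counted where the reported interval excluded 0. Of 773 values of all kinds, 493 stayed within the counting interval of the reported value and 249 left it without turning. RNA depth left rare sarcomere genes with too few UMIs for values per nucleus. Except where said, the cause was not tested.

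The share of fibroblast-like or cycling nuclei (93.6%) was 90.6% at resolution 0.3, 87.3% at 1.0, 65.0% with 15 components and 76.0% without high doublet scores; without cardiomyocyte-like nuclei these were 90.6%, 94.4%, 94.3% and 94.7%. In the last 3 settings, 7 of the 8 cardiomyocyte-like nuclei, with 511 UMIs of Myh6, lay in clusters that were named fibroblast-like without them. Without mitochondrial UMIs in the total, Tbx5 was 86.3 CPM and Ybx1 45.2, by construction, and the mean over nuclei of Ybx1 was 47.9 CPM.

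The myofibroblast median in ATAC cluster 4 (0.95) was 0.67 at resolution 0.3, 0.9996 at 1.0, 1.01 with components 2 to 15, 0.99 without high doublet scores, 1.02 and 0.99 in nuclei with Xist and with Y-linked RNA, 0.83 without smooth muscle- or pericyte-like nuclei, and 0.62 with ATAC counts thinned. The sarcomere median in ATAC cluster 2 (0.67) was 0.15 at resolution 0.3, 1.23 at 1.0 and 0.030 with components 2 to 15. It was 1.27 and 0.41 in nuclei with Xist and with Y-linked RNA, cardiomyocyte-like ones included. With ATAC counts thinned it was 0.52, and without cardiomyocyte-like nuclei 0.28. The cardiomyocyte marker promoters in RNA cluster 2 (0.45) were at 0.71 in nuclei with Y-linked RNA. At resolution 0.3 ATAC clusters 1 and 2, and 3 and 4, merged, and with ATAC counts thinned 3 and 4 merged, so those values are of merged clusters of 3101, 2545 and 2228 nuclei, which shows the cause. Against cluster 1 alone the cluster merged at resolution 0.3 had the other sign for sarcomere (0.15), calcium handling (0.33) and other reprogramming genes (0.099). Against cluster 3 this held for myofibroblast (0.67), calcium handling (-0.44), other reprogramming (-0.060) and sarcomere genes (-0.093) at resolution 0.3, and for the first 3 with ATAC counts thinned (0.62, -0.39 and -0.029). Against cluster 4 it held for immediate early genes (-0.088 and -0.096) and, with ATAC counts thinned, sarcomere genes (0.0092).

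In the parts matched at resolution 1.0, directions turned for G2 and M and S phase genes in ATAC clusters 1 (-1.37 and -0.25) and 2 (-1.25 and -0.49) and for fibroblast genes in cluster 3 (-0.13). With components 2 to 15 they turned for G2 and M (-0.33), S phase (-0.061) and immediate early genes (0.0019) in cluster 1 and other reprogramming genes in cluster 2 (-0.019). They also turned for sarcomere genes in cluster 3 with Xist (-0.66) and, with Y-linked RNA, for calcium handling in cluster 1 (0.033) and natriuretic peptides in cluster 2 (-0.054). These splits by sex-linked RNA include the cardiomyocyte-like nuclei.

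For nuclei with Tbx5, the myofibroblast median (-0.36) was -0.53 with 2 or more UMIs, -0.15 in the largest RNA cluster, -0.31 in fibroblast-like clusters and -0.33 with Y-linked RNA. The G2 and M median (0.43) was 0.83 with 2 or more UMIs, 0.76 thinned to 10200 UMIs and 0.23 with Xist, and turned to -0.14 in the largest cluster and -0.22 without the cycling cluster; the S phase median turned to -0.027 in the largest cluster. For Ybx1, the G2 and M median (1.07) was 0.86 without thinning, 2.12 with 2 or more UMIs, 0.89 thinned to 10200 UMIs, 0.69 without the cycling cluster and -0.43 in the largest cluster. The sarcomere median with Ybx1 (-0.22) turned to 0.010 in fibroblast-like clusters and 0.0022 without cardiomyocyte-like nuclei. The fibroblast list in nuclei with 5 or more sarcomere UMIs (21313 CPM) was 21680 without thinning, 14120 with the restricted list and 16090 with that list without cardiomyocyte-like nuclei.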

Other observations

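The tests with 2 or more Tbx5 UMIs and in the fibroblast-like clusters alone, the splits by sex-linked RNA, the values without cycling nuclei in ATAC cluster 5 and the genes of the unnamed cluster were chosen only after the data were seen. The unnamed cluster of 43 nuclei held genes of neutrophils: S100a9 was 1866 CPM against 1.46 in all other nuclei, S100a8 1112 against 0.940, and the proteases Elane and Prtn3 423 each against 0.0168 and 0.151. Such levels rested on few UMIs, as Lyz2, at 648 CPM in the same cluster, had 49. How many of the 43 nuclei held these genes is not given here, so a few may carry most of them. The gene models Gm42418 (23236 CPM against 5159), Gm26917 (12584 against 83.0) and AY036118 (7503 against 1810.3) were high in the unnamed cluster too. Its median depth was 1628 UMIs of RNA but 22382 ATAC counts, its median mitochondrial share was 2.06%, and its nuclei were spread over ATAC clusters 1, 2, 3, 4, 5 and 7 (3, 7, 7, 9, 11 and 6 nuclei). Endothelial-rich ATAC cluster 5 held more G2 and M RNA than all other nuclei (median log2 1.68, 1.48 to 1.84, 11 of 11 measured), but 10 of its 103 nuclei belonged to the cycling RNA cluster. Without these 10, against all nuclei outside ATAC cluster 5, the median was 0.54 (0.38 to 0.85), and in endothelial-like nuclei against all others 0.51 (0.32 to 0.83). With the cycling cluster left out of the other nuclei too, the medians were 2.54 (2.22 to 2.83) and 2.56 (2.20 to 2.85), with 4 of 13 genes measured in each. That cluster was named from these G2 and M genes, and 0 of the endothelial-like nuclei belonged to it. Leaving it out takes cycling nuclei from the comparison side, so a rise was built in and nothing is concluded from it.

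Cells of both sexes were present: 2364 nuclei (40.3%) held Xist, the RNA of X inactivation, without Y-linked RNA, and 2204 (37.6%) Y-linked RNA without Xist. Fibroblast-like nuclei were 85.3% of the former and 85.8% of the latter, RNA cluster 2 was 35.7% and 33.1%, and cluster 3 was 12.4% and 14.5%. At least 3 UMIs of both were held by 206 nuclei (3.51%), of which 23.8% were among the highest doublet scores, against 3.04% of nuclei with one sex's RNA.

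Nuclei with a Tbx5 UMI held less myofibroblast RNA (median log2 -0.36). A higher share of cycling nuclei was argued against, since the median was -0.38 (-0.41 to -0.36) without the cycling cluster, and so were cell types other than fibroblasts as the whole cause, since it was -0.31 (-0.34 to -0.30) in the fibroblast-like clusters alone. A difference between those clusters stays open: within RNA cluster 1 the median was -0.15 (-0.19 to -0.13), an interval that crosses the bound of -0.18 set beforehand, so fibroblast-like nuclei of other kinds may account for part of it and cannot be told apart from Tbx5 itself. With 2 or more Tbx5 UMIs the median was -0.53 (-0.57 to -0.50), as a difference that grows with Tbx5 RNA would give, which mixed fibroblast-like nuclei could give too. No untreated library was analysed here, so an effect of Tbx5 stays a hypothesis.

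Nuclei with a Ybx1 UMI held more S and G2/M RNA. Cell types other than fibroblasts were argued against as the whole cause, since in the fibroblast-like clusters alone, cycling ones included, the S phase median was 0.82 (0.59 to 0.92). Without the cycling cluster the G2 and M median was 0.69 (0.44 to 0.84), an interval that spans the bound of 0.54 set beforehand, so a single cluster of cycling nuclei may not be the whole source but is not excluded. Within RNA cluster 1 the S phase median was 0.16 (0.00 to 0.50), which decides neither for nor against other nuclei that cycle more, while the G2 and M median was -0.43 (-0.88 to 0.14), as such nuclei would give, though clusters made from RNA part cycling nuclei by construction. A cycling cluster and other nuclei that cycle more stay open, and a link between the Ybx1 RNA left in a nucleus and its cycling stays a hypothesis, for which no biological explanation was tested.

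The open peak near the end coordinate of Tbx5 may come from delivered Tbx5 DNA as well as from the mouse's own gene. Its share of nuclei with 6 or more counts was 11.7%, at percentile 96.4 of 167 peaks with like counts (median 7.31%), as delivered DNA in many copies would give, though some other peaks reached as much. The peak held 11671 counts against a median of 10154 in the matched peaks, which raises the share by itself. Of the 20 matched peaks with more counts, 14 had a lower share and the others did not. A difference between RNA clusters was argued against as the whole cause of its link to Tbx5 RNA. The log2 ratio within RNA cluster 1 was 0.27 (0.12 to 0.42), where the other peaks of the gene were at 0.03 (-0.10 to 0.16). A difference within RNA cluster 1 stays open, since 169, 640, 1129 and 220 of its nuclei lay in ATAC clusters 1 to 4. Those ATAC clusters held 96.4, 101, 66.8 and 32.6 CPM of Tbx5 RNA. The level of the peak near the end coordinate was 80.8 CPM in thinned nuclei with 0 Tbx5 UMIs. With 1, 2 and 3 or more it was 94.5, 94.2 and 92.5, so it did not rise further with Tbx5 RNA. No biological explanation was tested.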
